A study of Mus musculus with 2 samples.

How the data were processed

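Pancreatic islets of 6 to 8 wild-type male C57BL/6J mice were pooled and dissociated, and live CD45+ Epcam− cells were sorted and stained with oligonucleotide-barcoded antibodies, per the labels. The series holds 1 sample of cells read as 2 libraries, an mRNA library and an antibody library (ADT, antibody-derived tags), so no mouse, day or group was replicated. Per the labels' extract protocol the antibodies were against CD9 and CD206, whereas the design text names a CD9 antibody alone, and the matrix holds both tags.

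The deposited values are counts of unique molecular identifiers (UMIs) per gene or tag and cell, made by the authors with Cell Ranger 8.0.1, per the file headers. The genome build was mm10, per the submitters' processing notes. The matrix held 32285 genes, 2 antibody tags and 2237 barcodes, and the rule by which the authors kept barcodes is not given in the sources used here. Gene symbols were taken from the feature table of the same deposit. Where 2 gene IDs shared a symbol, the ID with more UMIs kept it, which affected 40 symbols.

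Cells were kept with at least 200 genes and at most 10% mitochondrial UMIs, which 2215 of the 2237 barcodes met. Doublets were scored with Scrublet as run by scanpy 1.11.5. Its automatic threshold marked 5 cells (0.226%), under the 0.5% set before the data were examined as the least that would be accepted, so the highest-scoring 1.79% (0.8% per 1000 barcodes) were removed instead, 40 cells in all. The 2175 remaining cells were log-normalised, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (leidenalg 0.10.2) were used. The genes of the antioxidant, endocrine and acinar lists, Cd9 and Mrc1 were left out of the clustering (77 genes), so that their levels could be compared between clusters.

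Clusters were named from marker lists fixed before the data were examined, and every name is to be read as "X-like". A marker counted for a cluster when at least 25% of its cells held a UMI and its CPM, with 10 added, was at least 2 times that of the reference cells, and at least 3 markers were needed. The reference was all other cells, except for macrophage-like clusters, which were compared with lymphoid and non-immune cells. A name other than macrophage-like also needed 0.5 of its listed markers and a share of passing markers at least 0.2 above that of the next type. Clusters stayed unnamed when that margin was missing, or when their median UMI count was under the sample's divided by 3 and none of their 10 leading genes was a marker of the name. These marker thresholds were set after the cells had been seen, and 3 clusters (237 cells) stayed unnamed.

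Levels are UMIs summed over the cells of a class and scaled to the class's total (CPM). Ratios of 2 sums carry exact conditional binomial 95% intervals, sums exact Poisson intervals and shares of cells exact Clopper-Pearson intervals. With 1 sample all of these cover counting error only, and no test, p-value or standard error was computed from cells. For each gene list fixed beforehand, the median log2 ratio over members with at least 20 UMIs in the 2 sums was computed, with an interval from 1000 Poisson redraws of the sums. Its percentile among 10000 random lists of the same size, drawn within 100 genes of each member's mean expression on either side, describes these libraries only. Where a sum was 0, the ratio was computed against a floor of 3 counts over that sum and is given as a bound.

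Macrophage-like cells were ranked by CD9 antibody UMIs within deciles of their RNA UMI total, and the highest and the lowest tercile were compared, so that their median RNA depths were nearly equal (20795 and 20774.5 UMIs), although the RNA UMIs summed over the 556 cells of each were 12130844 and 11528784. The same was done for CD206. A tercile is a range of a continuous score, not a cell type.

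Genes named from the lists had at least 100 UMIs in the 2 sums and a ratio of at least 1.5 either way, at most 4 per list and direction, ordered by the interval bound nearest to 1. From all genes, the 12 higher and the 12 lower genes by the same bound were taken for each antibody, leaving out mitochondrial, ribosomal protein, endocrine and acinar genes; 1 gene that met this rule is not reported here. A fixed set of antioxidant and antibody-target genes (Cd9, Mrc1, Nfe2l2, Keap1, Hmox1, Nqo1, Gclc, Gclm, Prdx1, Gpx1, Gpx4, Sod1, Sod2, Cat, Txnrd1, Srxn1 and Slc7a11) could be named whatever their ratio.

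The ratio and list steps were tested on simulated counts in which 200 genes were changed by known folds. These counts were Poisson draws of summed UMIs from a shared profile, with no variation between cells and no genes that vary together. The shares below therefore check the computation, and not how well the intervals or percentiles hold where cells vary or listed genes go together. For the CD9 comparison (8947 genes), the simulated ratio lay inside the interval for 95.7% of unchanged genes, 92.5% of genes changed 1.5-fold, 98.5% of those changed 2-fold and 98.5% of those changed 4-fold. An estimated ratio of 1.5 or more, either way, was reached by 0.183% of unchanged genes and by 100% of those changed 2-fold. For macrophage-like against other immune cells (10200 genes), these shares were 4.71% of unchanged genes and 94% of genes changed 2-fold. Of 100 random lists of 18 unchanged genes, 7 fell outside the central 95% of matched lists in the CD9 comparison and 4 in the other.

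Alternatives fixed beforehand covered the cell filters, doublet removal, clustering resolution, clustering features, the averaging over cells, the list minimum, cells rich in endocrine RNA and the way CD9 was ranked. Leaving out cycling macrophage-like clusters could not be run as an alternative, since no macrophage-like cluster had 3 cycling markers. Further alternatives were added after the data were seen. The spread between the highest and the lowest list in CD9-high against CD9-low cells, by which alternatives are compared for the lists as a set, was also defined after the list medians were seen. Free RNA was not subtracted. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9 and matplotlib 3.10.9.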

Results

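Immune cells sorted from the pancreatic islets of wild-type mice were profiled by single-cell RNA sequencing together with surface CD9 and CD206, read as antibody-derived tags. CD9 is a tetraspanin membrane protein and CD206 (encoded by Mrc1) is the macrophage mannose receptor. The series title concerns an antioxidant program of islet-resident macrophages, and the comparisons ask where antioxidant genes were high among the sorted cells and whether they differed with surface CD9. The mRNA library had a median of 19352 RNA UMIs per barcode (quartiles 13191 and 24852), and 2175 cells were kept. The antibody library gave a median of 379 CD9 UMIs and 7 CD206 UMIs in the kept cells. The cells of 6 to 8 mice were pooled into 1 sample, so every interval below covers counting error only and no difference has a replicate check.

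Macrophage-like cells made up 76.6% of the kept cells (1666 of 2175, 95% interval 74.8 to 78.4%). They formed 9 clusters, in each of which 11 of the 12 macrophage markers, among them Adgre1, the complement genes C1qa, C1qb and C1qc, and Csf1r, were enriched over lymphoid and non-immune cells. Other immune classes were T cell-like (77 cells, 3.54%), NK cell-like (41 cells, 1.89%), cDC2-like (a class of conventional dendritic cell, 39 cells, 1.79%), B cell-like (29 cells, 1.33%) and monocyte-like (17 cells, 0.782%) cells. Despite the CD45+ Epcam− gate, 45 endocrine-like and 24 endothelial-like cells were present. The endothelial-like cells also held C1qa at 611 CPM and Lyz2 at 625 CPM, against 64.0 and 14.7 CPM in T cell-like cells. Their levels, CD9 included, may therefore not be those of endothelial cells alone, and the cause was not tested. T cell markers (5 of 10) also passed in the NK cell-like cluster, and 4 neutrophil markers passed in the monocyte-like cluster. In the cDC2-like cluster (cluster 13) all 8 cDC2 markers passed, but so did 4 migratory dendritic cell markers, and its 10 leading genes held 2 of these (Ccr7 and Il4i1) and 1 cDC2 marker (Cd209a), so that its name among dendritic cells is uncertain. Among the 237 unnamed cells, 145 formed a cluster with a median of 3940 UMIs and 38 a cluster with a median of 1230.5 UMIs, in which 9 and 7 macrophage markers passed, and 54 formed a cluster with 5 cDC2 markers, 4 cDC1 markers and 8 of the 9 cycling markers. The sort sets which types could appear, so the shares describe the sorted suspension and not the islet. Macrophage transcripts were also counted in lymphoid cells, a measure of free RNA in the suspension, which was not subtracted: in T cell-like cells (median 9145 UMIs) C1qa stood at 64.0 CPM and Apoe at 419 CPM, against 2522 and 8858 CPM in macrophage-like cells (median 20777.5 UMIs).

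Surface CD9 was higher on macrophage-like cells than on the other immune cells together. Macrophage-like cells carried a mean of 1685 CD9 UMIs (1683 to 1687) and the 203 other immune cells a mean of 510, a ratio of 3.30 (3.28 to 3.32). Within the macrophage-like class the level ranged widely, with quartiles of 84.25 and 2241.75 around a median of 624. T cell-like and B cell-like cells had medians of 46 and 25 CD9 UMIs, NK cell-like cells 137 and monocyte-like cells 70, while cDC2-like cells had 739 and endothelial-like cells 914.5. The cDC2-like cells carried most of the signal of the other immune cells: without them, a setting chosen after the data were seen, the ratio of means was 9.94. The ratio was 8.91 for medians over cells, 2.06 per RNA UMI, 2.14 at clustering resolution 0.5, where 56 cells were cDC2-like, and 1.71 with at least 500 genes per cell, where 71 were. Cd9 mRNA did not follow this difference, at 216 CPM in macrophage-like and 203 CPM in other immune cells (ratio 1.06, 0.98 to 1.16). CPM is scaled to RNA UMIs, so its counterpart is the antibody ratio of 2.06 per RNA UMI and not the 3.30 per cell. The mRNA ratio joined opposite differences: Cd9 stood at 54.7 CPM in T cell-like and 102 CPM in B cell-like cells, but at 237 CPM in cDC2-like, 333 CPM in NK cell-like and 438 CPM in monocyte-like cells. CD206 had a mean of 26.1 UMIs on macrophage-like cells and 6.12 on other immune cells (ratio 4.27, 4.04 to 4.52), with medians of 9 and 1 and 1.23 and 0.463 UMIs per 1000 RNA UMIs, and Mrc1 mRNA stood at 32.6 and 6.70 CPM (ratio 4.87, 3.07 to 8.24).

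**Figure D1:**
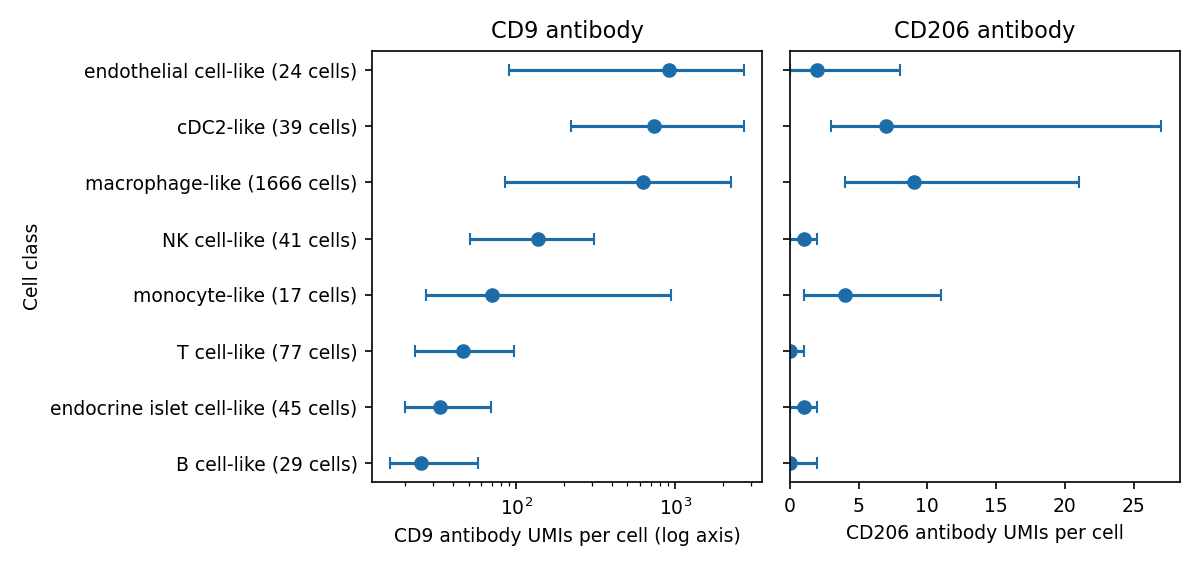
Antibody UMIs per cell for CD9 (log axis) and CD206 (linear axis) in each named class of cells, with points for medians and bars for the quartiles over cells. The CD9 medians of endothelial-like (914.5), cDC2-like (739) and macrophage-like cells (624) lie above those of lymphoid classes (25 to 137).

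Antioxidant genes were higher in macrophage-like cells than in the other immune cells, most clearly the targets of NRF2, the transcription factor that responds to oxidative stress. Of 18 NRF2 target genes, 17 were at least 1.5-fold higher and none was as much lower, with a median log2 ratio of 1.51 (1.45 to 1.60), above all 10000 matched random lists. Prdx1 (ENSMUSG00000028691), a peroxiredoxin that reduces hydrogen peroxide, stood at 4790 CPM against 822 CPM (ratio 5.83, 5.59 to 6.08). Hmox1 (ENSMUSG00000005413), the heme-degrading enzyme, stood at 3386 against 629 CPM (5.38, 5.13 to 5.65). Srxn1, which restores oxidised peroxiredoxins, was 5.27-fold higher (4.59 to 6.08), and Blvrb, a biliverdin reductase, 5.13-fold higher (4.33 to 6.12).

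Over all 44 measured antioxidant genes the median log2 ratio was 0.71 (0.61 to 0.87), with 24 genes at least 1.5-fold higher and 8 as much lower. In the glutathione system (median log2 0.41, 7 higher and 3 lower of 16), the subunits of the enzyme that starts glutathione synthesis were higher, Gclc 2.67-fold and Gclm 2.34-fold, with Glrx at 1.99-fold, whereas Gpx4 was lower (142 against 217 CPM, ratio 0.656). Mgst1 was also lower (ratio 0.269), but not once monocyte-like cells were left out. The peroxiredoxin and thioredoxin genes went both ways around a median log2 of 0.03 (4 higher and 5 lower of 12): besides Prdx1 and Srxn1, Txnrd1 was 2.74-fold and Prdx4 1.90-fold higher, while Prdx6 (103 against 336 CPM, ratio 0.307), Txnip (0.447), Prdx3 (0.478) and Prdx2 (0.559) were lower. Sod2, the mitochondrial superoxide dismutase, was 2.02-fold and catalase (Cat) 1.89-fold higher, in a list of 4 measured genes with a median log2 of 0.43. Nfe2l2, which encodes NRF2, was 1.74-fold higher, Keap1, its repressor, 1.77-fold and Slc7a11, the cystine importer, 1.53-fold, whereas Gpx1 (1.03), Sod1 (0.851) and Nqo1 (log2 0.32, interval of the ratio 0.889 to 1.81) were under 1.5-fold apart from the other immune cells together. For Gpx1 this joined opposite differences, since macrophage-like cells (371 CPM) stood above T cell-like (109 CPM), B cell-like (102 CPM) and NK cell-like cells (49.0 CPM) and below cDC2-like (464 CPM) and monocyte-like cells (1505 CPM). The ratio of Slc7a11 (355 CPM in macrophage-like cells) also joined opposite differences. It had 0 UMIs in T cell-like, NK cell-like and B cell-like cells, but 322 CPM in cDC2-like and 1212 CPM in monocyte-like cells. Without the cDC2-like cells the log2 ratios of Sod1 and Nqo1 were 0.11 and 1.63. With at least 500 genes per cell the median over all antioxidant genes was 0.47.

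Against T cell-like, NK cell-like and B cell-like cells the NRF2 target genes had median log2 ratios of 3.77, 3.58 and 3.52, or 3.25, 3.10 and 3.41 with genes at 0 UMIs set to the floor of 3 counts over the class. Against cluster 13, cDC2-like with migratory dendritic cell markers, the median ratio was 2.37-fold, or 1.19 on the log2 scale at the floor. Against the 17 monocyte-like cells it was −0.14 (−0.41 to 0.14), and over all antioxidant genes −0.37 (−0.67 to −0.30; −0.53 at the floor), with 9 genes at least 1.5-fold higher in macrophage-like cells and 18 as much lower. The 9 include Gstm5, Gstk1 and Gstt1, which had 0 UMIs in monocyte-like cells. Their ratios at the floor were 0.499, 0.282 and 0.0478, so that they give no direction. Without the monocyte-like cells, a setting chosen after the data were seen, the median log2 ratio over all antioxidant genes against the other immune cells was 1.13.

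Most other lists were also higher in macrophage-like cells than in the other immune cells together, but not always than in each class. Of the genes named below, Cybb and Slc11a1 were higher in monocyte-like cells (1591 and 344 CPM) than in macrophage-like cells (1044 and 205 CPM). Inflammatory cytokine genes had a median ratio of 7.99-fold (12 higher and none lower of 14; log2 2.89 with the gene at 0 UMIs at the floor), led by Cxcl1 (137 against 0.744 CPM, 183-fold, 50.7 to 1515), Cxcl2 (3657 against 154 CPM, 23.7-fold), Il1a (34.3-fold) and Ccl3 (12.4-fold). Heme and iron genes had a median log2 of 2.16 (1.84 at the floor), with the iron exporter Slc40a1 13.6-fold and the phagosomal transporter Slc11a1 5.10-fold higher, and the transferrin receptor Tfrc lower (ratio 0.264). Lipid-associated macrophage genes had a median of 2.04 (15 of 17 higher), with Apoe 17.0-fold, Trem2 22.6-fold, Cd63 13.5-fold and Lpl 17.98-fold higher. MHC class II and costimulation genes had a median of 1.15, Cd74 being 2.77-fold higher, although Cd80 was lower (0.196), which was lost when the cDC2-like cells were left out. The cDC2-like cells stood close to macrophage-like cells in this list, with H2-Aa at 11707 against 11351.5 CPM and Cd74 at 23755 against 28372.5 CPM. Immediate-early and heat-shock genes, which tissue dissociation is known to induce, were also higher (median log2 1.13), with Hspa1b 19.5-fold and Atf3 6.78-fold. Selenop, a secreted selenium carrier, was 7.84-fold higher within a selenoprotein list of median 0.13. The medians were 0.46 for NADPH oxidase genes (Cybb 2.65-fold), 0.48 for interferon response genes (Rsad2 3.05-fold; Cxcl9 0.224, but at least 14.1-fold higher without the cDC2-like cells) and −0.03 for glycolysis genes (Ldha 0.487), and cycling genes were lower at −1.70 (Top2a 0.0589). Stromal resident macrophage genes had a median of 2.38 but a mean of −0.90, since genes at 0 UMIs in the other cells drop out of the mean, and the median was 1.24 with those at the floor of 3 counts over the class. Pf4 was at least 22.9-fold and Folr2 at least 7.63-fold higher, whereas Timd4 (0.0274), F13a1 (0.0882) and Mgl2 (0.117) were lower, each through 1 class. Without the cDC2-like cells Mgl2 was higher (log2 3.30) and Timd4 had 0 UMIs in the other cells, too few to give a direction, and without the monocyte-like cells the log2 ratio of F13a1 was −0.32 (−1.63 to 1.35). Growth factor genes had a median ratio of 2.39-fold, and Igf1, an insulin-like growth factor, had 460 UMIs in macrophage-like cells and 0 in other immune cells, at least 11.7-fold higher. Endocrine hormone genes had a median log2 of 1.48, which was 0.31 without the 10% of cells richest in endocrine and acinar RNA, and the 1 measured acinar gene stood at 0.14.

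Between the 9 macrophage-like clusters the NRF2 targets spread more widely than the other antioxidant lists. In cluster 5, led by Cxcl2 and Gdf15 among its defining genes, 10 of 18 NRF2 targets were at least 1.5-fold above the other macrophage-like clusters (median log2 0.62, 0.56 to 0.65). Hmox1 stood there at 7101 against 2951 CPM, Gclc at 626 against 247 CPM, Srxn1 at 694 against 366 CPM and Gclm at 511 against 281 CPM. In cluster 4, led by Cx3cr1 and Tgfbr1, 12 of 18 were lower (median log2 −1.22, −1.29 to −1.12), with Hmox1 at 798 against 3692 CPM (ratio 0.216), Slc7a11 at 0.231, Gclc at 0.295 and Srxn1 at 0.304 of the other clusters, and Prdx1 at 2051 against 5113 CPM. Gpx1, a glutathione peroxidase, and the thioredoxin inhibitor Txnip were higher in cluster 4 (1.70-fold and 2.33-fold). The interferon-led cluster 0 had a median of −0.44, and the heat-shock-led cluster 2 and the Pdpn- and Il10-led cluster 8 had 0.31 each.

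The glutathione system was highest in cluster 6, which was led by Pltp, Spp1 and Fabp5. Its median log2 ratio there was 0.47 (0.41 to 0.67), with 7 of 16 genes at least 1.5-fold higher, among them the glutathione transferases Mgst1 (6.44-fold), Gstm1 (2.19-fold), Gstp1 (2.10-fold) and Gsto1 (1.85-fold). Peroxiredoxin and thioredoxin genes had a median of 0.39 in the same cluster, while its Hmox1 (0.576) and Gclc (0.566) were lower than in the other clusters. Over all antioxidant genes the medians ran from 0.27 in cluster 6 to −0.84 in cluster 15 (−0.66 with the 3 genes at 0 UMIs at the floor), a spread of 1.11 (0.84 to 1.26). Cluster 15 held 31 cells with a median of 12666 UMIs, the fewest of the macrophage-like clusters, a median mitochondrial share of 1.71%, and higher endocrine hormone genes than the other clusters (median log2 1.17, 8 of 13 at least 1.5-fold higher). Immediate-early and heat-shock genes, which took part in defining the clusters, had medians of the same sign as the NRF2 targets in 6 clusters: cluster 5 (0.67), cluster 2 (1.90), cluster 4 (−1.92), cluster 0 (−0.80), cluster 3 (−1.65, NRF2 −0.10) and cluster 6 (−1.65, NRF2 −0.11). They had the other sign in cluster 15 (0.50, NRF2 −1.61), cluster 8 (−0.28, NRF2 0.31) and cluster 1 (−0.25, NRF2 0.20).

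**Figure D2:**
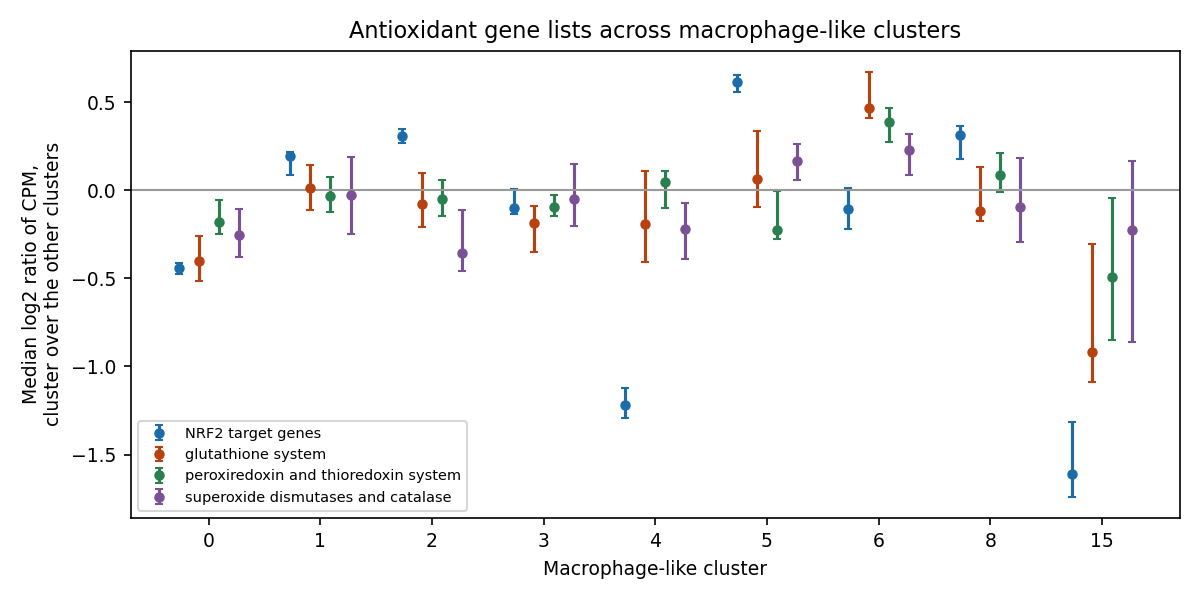
Median log2 ratio of CPM for 4 antioxidant gene lists in each macrophage-like cluster over the other macrophage-like clusters, with bars for the 95% interval of counting error. NRF2 target genes range from 0.62 in cluster 5 to −1.22 in cluster 4 and −1.61 in cluster 15, and the glutathione system is highest in cluster 6 (0.47).

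CD9-high and CD9-low macrophage-like cells were the highest and lowest tercile by antibody count, 556 cells each, with means of 4008 and 123 CD9 UMIs and medians of 20795 and 20774.5 RNA UMIs. Cd9 mRNA (ENSMUSG00000030342) went with the antibody, at 389 CPM in CD9-high and 53.4 CPM in CD9-low cells, a ratio of 7.29 (6.70 to 7.94). Over the deciles of the antibody it went from 11.6 CPM (8.34 to 15.8) to 444 CPM (423 to 466). The terciles are ranges of a continuous level, and 340 of the 1666 cells (20.4%) lay within 5 percentage points of a boundary. The ratio followed the width of the ranges, at 4.04 for the upper against the lower 50% of cells and 17.98 for the upper against the lower 20%, and it was 12.5 when raw antibody counts were ranked without regard to RNA depth.

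**Figure D3:**
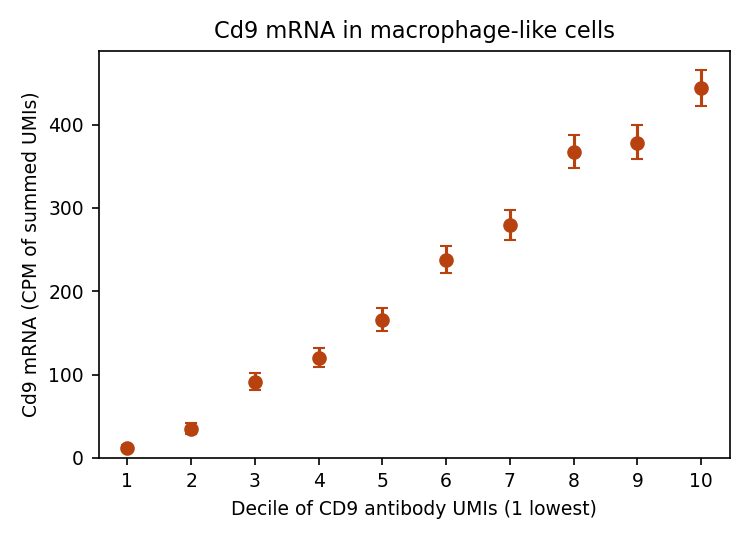
Cd9 mRNA (CPM of summed UMIs) in macrophage-like cells by decile of the CD9 antibody count, ranked within deciles of RNA UMIs, with bars for exact Poisson 95% intervals. The level goes from 11.6 CPM in decile 1 to 444 CPM in decile 10.

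Genes other than Cd9 that were higher in CD9-high cells included Slpi, a secreted protease inhibitor (48.8 against 4.08 CPM, 11.97-fold, 8.89 to 16.5), Pdpn, which encodes podoplanin (28.4 against 3.82 CPM, 7.45-fold), the kinase gene Ikbke (6.83-fold), Gpnmb, a lysosomal glycoprotein of lipid-laden macrophages (47.3 against 8.24 CPM, 5.74-fold), Clec4n (4.87-fold), S100a10 (4.68-fold), Sgms1 (4.81-fold) and Zfp366 (5.70-fold), with 4930523C07Rik (5.85-fold) and Gm43251 (6.59-fold). Lower in CD9-high cells were Frmpd4 (3.63 against 96.9 CPM, ratio 0.0374), Npnt, an extracellular matrix protein (3.87 against 80.5 CPM, 0.0481), Dlc1 (0.0646), the atypical cadherin Fat3 (10.3 against 96.8 CPM, 0.106), St5 (0.119), Wwtr1 (0.0941), Igf2bp3 (0.143), Ppp1r9a (0.142), Tspan7 (0.152), Lrrc3 (0.175) and Xlr (0.224). Racgap1 also met the rule (0.0820), but 133 of its 151 UMIs came from 1 CD9-low cell and the ratio without that cell was 1.90. For Slpi, Gpnmb and Gm43251, 1 cell held 20.2%, 18.8% and 25.2% of the UMIs. Without that cell their ratios were 9.38, 4.49 and 4.70. Slpi had a UMI in 49 of the 556 CD9-high and 14 of the 556 CD9-low cells. For Gpnmb these counts were 56 and 22, for Zfp366 40 and 8, and for Gm43251 11 and 5. Such genes mark a minority of CD9-high cells, while others were seen more broadly, such as Clec4n (223 and 67 cells).

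The antioxidant lists differed in direction between CD9-high and CD9-low cells, in which the median log2 ratio of all genes was 0.07. Glutathione system genes were higher in CD9-high cells, with a median log2 ratio of 0.29 (0.21 to 0.41) at the 99.7th percentile of matched random lists and 4 of 15 genes at least 1.5-fold higher. Gstm1 (37.1 against 20.1 CPM, 1.84-fold), Gstp1 (1.59-fold) and Gsto1 (1.53-fold), all glutathione transferases, led them. Peroxiredoxin and thioredoxin genes had a median of 0.26 (0.17 to 0.35), at the 99.9th percentile, led by Prdx6 (128 against 78.9 CPM, 1.62-fold) and Txnip (1.58-fold). NRF2 target genes had a median of −0.10 (−0.16 to −0.02), at the 16.4th percentile, and none of the 18 differed 1.5-fold: Hmox1 stood at 3007 against 3775 CPM (ratio 0.797), Prdx1 at 4611 against 5334 CPM (0.865), Gclc at 0.883, Txnrd1 at 0.867 and Srxn1 at 0.874, whereas Slc7a11 stood at 425 against 288 CPM (1.48) and Gclm at 1.17. Superoxide dismutases and catalase had a median of 0.05, with Sod1 at 0.978, Sod2 at 1.08 and Cat at 1.02. Gpx1 (1.23) and Gpx4 (1.26) were slightly higher, and Nfe2l2 (1.01), Keap1 (0.968) and Nqo1 (0.993) were nearly equal. Over all 43 measured antioxidant genes the median log2 ratio was 0.16 (0.09 to 0.21), with 6 genes at least 1.5-fold higher and none as much lower. With terciles ranked within each cluster that median was 0.09, and the NRF2 median was 0.02 when raw antibody counts were ranked. With cells ranked by Cd9 mRNA instead of the antibody, a test chosen after the data were seen, the NRF2 median was 0.12 (0.08 to 0.16), so that its direction depended on the measure of CD9.

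Inflammatory cytokine genes were lower in CD9-high cells, with a median log2 ratio of −0.54 (−0.60 to −0.48) below every matched random list, and 6 of 13 at least 1.5-fold lower. Il1a stood at 115 against 302 CPM (ratio 0.380), Cxcl1 at 86.6 against 226 CPM (0.383), Ccl3 at 737 against 1517 CPM (0.486) and Cxcl2 at 2373 against 4781 CPM (0.496). Immediate-early and heat-shock genes were lower as well (median −0.23), with Atf3 at 0.546, Nr4a1 at 0.562 and Egr1 at 0.601. Glycolysis genes were higher (median 0.27, 99.9th percentile), with Eno1 1.53-fold. Lipid-associated macrophage genes had a median of 0.13 but went both ways: besides Gpnmb, Spp1 was 2.49-fold, Trem2 1.80-fold and Ctsd 1.75-fold higher, while the fatty acid transporter Cd36 (411 against 1246 CPM, 0.330) and the lipase Lpl (0.438) were lower, as was the iron exporter Slc40a1 (0.505) in a heme and iron list of median −0.04. Without the 1 cell that held 18.6% of its UMIs, Spp1 was 1.86-fold higher. Stromal resident genes (−0.06) held Mgl2 at 1.74-fold and Pf4 at 0.515. The medians were 0.04 for MHC class II and costimulation (Cd80 2.30-fold), 0.04 for selenoproteins, 0.11 for NADPH oxidase, 0.01 for growth factors and 0.20 for cycling genes (Mki67 2.32-fold). Interferon response genes had a median of −0.09 and a mean of 0.07, with Cxcl9 3.56-fold higher. Without the 1 cell that held 27.0% of its UMIs, Cxcl9 was 2.35-fold higher. The spread between the highest and the lowest list, a summary defined after the list medians were seen, was 0.83 (0.73 to 0.96), and no acinar gene had enough UMIs. Endocrine hormone genes had a median of −0.45, resting on few cells: 1 cell held 49.1% of the Ppy UMIs, and the median was 0.04 without the 10% of cells richest in endocrine and acinar RNA. The median endocrine share per cell was 0.0971% in CD9-high and 0.104% in CD9-low cells.

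**Figure D4:**
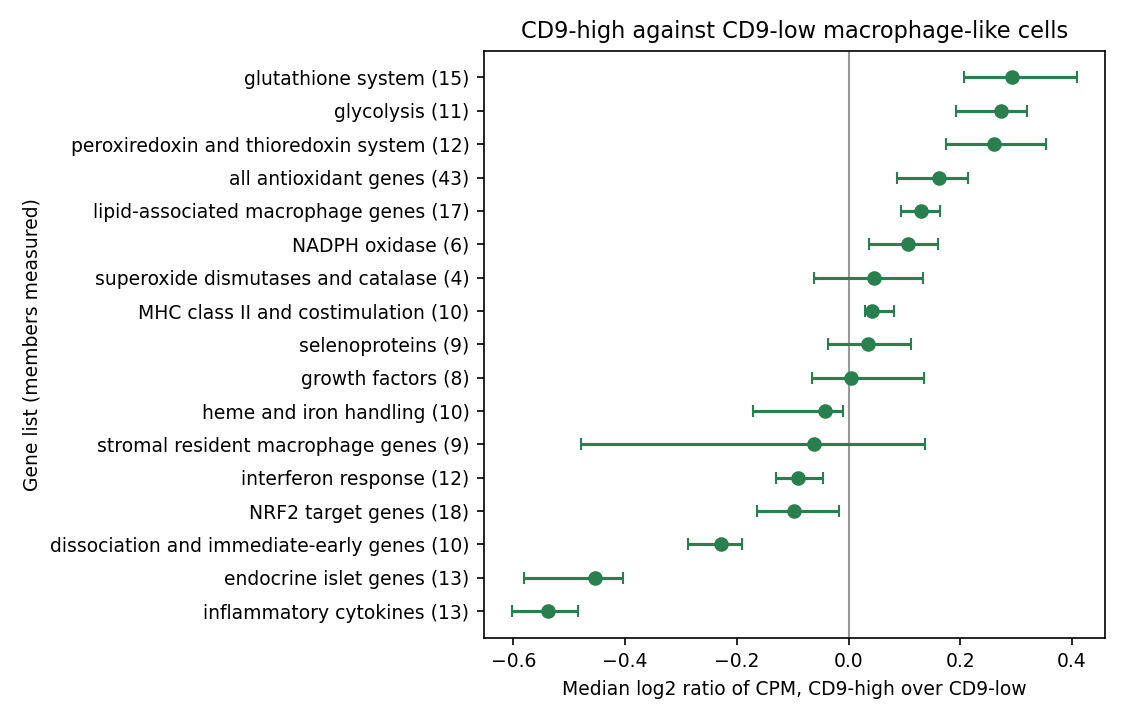
Median log2 ratio of CPM in CD9-high over CD9-low macrophage-like cells for each gene list, with the number of measured members in brackets and bars for the 95% interval of counting error. The glutathione system (0.29) lies at the upper end and inflammatory cytokines (−0.54) at the lower end.

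The clusters held unequal shares of CD9-high cells. Of the Pltp- and Spp1-led cluster 6, 60.3% of cells were CD9-high (52.1 to 68.0%), against 19.9% of cluster 3 (14.7 to 25.9%), which was led by Il12b and Mmp13, and 25.1% of cluster 1, led by Slc40a1 and Cd36. With terciles ranked within each cluster, Cd9 mRNA was still 4.87-fold higher, the glutathione median was 0.23, the inflammatory median −0.29, the glycolysis median 0.12 and the lipid-associated median 0.01. The low-count stromal resident list was then the lowest at −1.42 (−1.76 to −1.03), the interferon median had the other sign (0.11, 0.09 to 0.15) and the growth factor median was −0.17.

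CD206-high and CD206-low macrophage-like cells, again 556 each, differed most in Mrc1 (ENSMUSG00000026712), at 67.6 against 5.11 CPM (13.2-fold, 10.2 to 17.5). Stromal resident macrophage genes were higher in CD206-high cells (median log2 1.48, 0.93 to 1.88, above all matched random lists, 8 of 12 at least 1.5-fold higher), among them Mgl2 (4.22-fold), Cbr2 (3.13-fold, and 1.70-fold without the 1 cell that held 34.9% of its UMIs) and Pf4 (1.65-fold). Cluster 6, in which this list was 6.90-fold above the other clusters, had 59.6% CD206-high and 18.6% CD206-low cells, and cluster 1 (median −2.49) 17.3% and 43.2%. In settings chosen after the data were seen, the median was 1.12 (0.79 to 1.57) with terciles ranked within each cluster but 0.21 (−0.02 to 0.36) without cluster 6, so that it rested largely on that cluster, while the log2 ratio of Mrc1 was 3.12 and 3.48. Fabp4, a fatty acid binding protein, was 6.98-fold, Ednrb 5.52-fold, Tmem26 7.24-fold, Dgkg 5.96-fold, Pdlim1 5.28-fold, Gpr141 5.13-fold, Ampd3 4.79-fold, Prkg1 3.54-fold, Nav1 3.32-fold, Ahnak 2.88-fold and the growth factor Igf1 2.28-fold higher. Frmpd4 (0.220), Npnt (0.219), Fat3 (0.227), St5 (0.279), Mmp10 (0.244), A4galt (0.346), Speg (0.347), Nes (0.418), Fam189a2 (0.432), the integrin gene Itgb8 (0.449) and Lpl (0.400) were lower, as was Racgap1 (0.0877), of which 1 cell held 85.3% of the UMIs and which was not lower without that cell. For Fabp4, Tmem26 and Mmp10, 1 cell held 25.2%, 25.5% and 27.7% of the UMIs. Without that cell their ratios were 4.98, 5.16 and 0.373. Antioxidant genes differed little, with a median log2 of 0.04 over all 43 and Hmox1 at 1.02, and both had the other sign within clusters (−0.02 and −0.08). Endocrine hormone genes had a median of −0.67, or 0.14 within clusters, with nearly equal median shares per cell (0.0986% and 0.104%), and heme and iron genes a median of 0.03 but a mean of −0.06. CD206-high cells also carried more CD9 antibody (mean 2596 against 1004 UMIs) and more Cd9 mRNA (1.45-fold). CD206 counts were low, with medians of 29 and 2.5 UMIs per cell in the 2 terciles, and 340 cells again lay near a boundary.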

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

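The settings that matched CD206 or the dissociation genes, ranked CD206 within clusters, left out cluster 6, cluster 15, a class or the top cell, or added low-depth clusters were chosen after the data were seen, as was the spread between lists as a summary. No paired analysis was possible because there is 1 sample. No alternative reversed a main comparison, but several moved beyond counting error. For the share of cells and the spreads between lists and between clusters, which cannot be negative, a reversal was not possible. Macrophage-like cells made up 79.7% with at least 500 genes, 78.4% with all variable genes used for clustering and 85.0% with low-depth clusters added. The CD9 protein ratio of macrophage-like over other immune cells was 1.71 with at least 500 genes, 2.77 with at most 5% mitochondrial UMIs, 4.10 with doublets kept, 2.14 at resolution 0.5, 4.47 with all variable genes, 2.06 per RNA UMI, 8.91 for medians and 9.94 without cDC2-like cells. The cDC2-like class held 39 cells in the main clustering and 71, 45, 36, 56 and 36 under the 5 clustering changes in that order, and the cause was not tested further.

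The median log2 ratio of antioxidant genes in macrophage-like against other immune cells was 0.47 with at least 500 genes, 0.59 with at most 5% mitochondrial UMIs, 0.56 at resolution 0.5, 0.91 as a mean over cells and 1.13 without monocyte-like cells. In CD9-high against CD9-low cells it was 0.24 for raw CD9 counts and 0.0864 within clusters. The Cd9 mRNA ratio was 6.58 with doublets kept, 12.5 for raw counts, 4.04 for 50% ranges, 17.98 for 20% ranges, 4.87 within clusters, 6.38 with CD206 matched and 8.50 without cluster 6. The spread between gene lists in that comparison was 1.65 within clusters, 1.29 with CD206 matched and 1.02 with dissociation genes matched, since the low-count stromal resident list then had medians of −1.42, −1.04 and −0.73. The spread between clusters was 0.98 at resolution 0.5, within counting error of 1.11. For these moved values other than the spread between lists, the cause was not tested.

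Of the log2 ratios whose counting interval excluded 0, 23 values under alternatives had the other sign, and the cause was not tested. A further 50 values with the other sign belong to ratios whose interval spanned 0, such as growth factors in the CD9 comparison and the glutathione, heme and iron and lipid-associated lists in the CD206 comparison, and are not listed. In CD9-high against CD9-low cells these were, without the cells richest in endocrine RNA, the endocrine list (0.0419), Ppy (0.00775) and Pyy (0.24); for raw counts, the NRF2 list (0.0247); within clusters, MHC class II (−0.00056), the interferon list (0.11) and Mrc1 (−0.0440); with CD206 matched, MHC class II (−0.0021) and Mrc1 (−0.77); and without its top cell, Racgap1 (0.92). In macrophage-like against other immune cells these were, without monocyte-like cells, Fabp4 (3.45) and Mgst1 (1.17), and without cDC2-like cells, Cd80 (0.19), Mgl2 (3.30), Sod1 (0.11) and Cxcl9 (at least 3.82, against 0 UMIs). In CD206-high against CD206-low cells these were, within clusters, growth factors (−0.0701), the endocrine list (0.14), all antioxidant genes (−0.0185), Hmox1 (−0.0783), Ins1 (0.000878) and Ins2 (0.0330), and without cluster 6, the dissociation list (0.00466). The stromal resident median in that comparison was 1.12 within clusters and 0.21 without cluster 6, against 1.48. Of 1088 values of 68 single genes across alternatives in the CD9 comparison, 799 stayed within counting error. In macrophage-like against other immune cells 490 of 720 values of 80 genes did, and in the CD206 comparison 65 of 112 values of 56 genes. Leaving out cycling macrophage-like clusters gave no value, as there were none. Classes of 17 to 77 cells limit every comparison with single other types.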

Other observations

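The tests of unspecific antibody binding by CD206 and by Cd9 mRNA, of free RNA and of a few cells with much endocrine RNA, the ranking of dissociation genes over all cells, the limits of 0.5% and 1% endocrine UMIs and the Ins2 to Gcg ratio were chosen after values they bear on had been seen.

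Monocyte-like cells, 17 cells with a median of 14250 UMIs, had the highest level of several antioxidant genes among the named classes taken whole, although the macrophage-like clusters 5 (7101 CPM), 2 (6488 CPM) and 8 (4643 CPM) stood higher in Hmox1. Hmox1 stood at 4233 CPM against 3386 CPM in macrophage-like cells (interval of the ratio of macrophage-like over monocyte-like 0.753 to 0.850), Slc7a11 at 1212 against 355 CPM (ratio 0.293), Gpx1 at 1505 against 371 CPM (0.246), Gclm at 703 against 305 CPM (0.433) and Sod2 at 912 against 377 CPM (0.413). Nfe2l2 itself stood at 1773 against 966 CPM. Prdx1 was the other way round, at 4790 CPM in macrophage-like and 2899 CPM in monocyte-like cells (1.65, 1.54 to 1.78), as was Srxn1 (2.36). The chemokine genes Ccl3 (31.7-fold) and Ccl4 (34.8-fold) were higher in macrophage-like cells, whereas Il1b was nearly equal (0.862). Mgst1 (130 against 3.71 CPM), Gsr (742 against 204 CPM) and Ccl4, outside the naming rule for this pair of classes, were chosen after their values were seen.

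Across macrophage-like clusters Cd9 and Mrc1, neither of which took part in the clustering, were both highest in cluster 6. Cd9 stood there at 422 CPM (401 to 443) against 317 CPM in cluster 8 and 144 to 250 CPM in the other clusters, and Mrc1 at 77.9 CPM (69.1 to 87.5) against 15.9 to 49.6 CPM. The median CD9 antibody count was 2793 UMIs in cluster 6, 1911 in cluster 8 and 185 in cluster 1.

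NRF2 target genes differed between macrophage-like clusters, with RNA depth and cell handling as candidate explanations. The tables argue against RNA depth as the whole cause of the difference between clusters 5 and 4: among cells with 15000 to 20000 RNA UMIs (38 and 73 cells), the median log2 ratio of cluster 5 over cluster 4 was 1.37 (1.09 to 1.53), against 1.57 at all depths. No other clusters were compared at matched depth. Cluster 15, the lowest in NRF2 targets, also had the lowest depth of the macrophage-like clusters (median 12666 UMIs), so depth stays open there. Handling is argued against within clusters only, as far as immediate-early and heat-shock genes measure it. There, the tercile of cells with the highest share of these genes had lower NRF2 targets than the lowest tercile (median log2 −0.19, −0.22 to −0.11), although Hmox1 was 1.10-fold higher. That ranking leaves out the differences between clusters, which these genes helped to define, so it cannot decide the cause of the pattern. Between clusters both groups of genes had the same sign in 6 of 9. That count cannot decide, since the clusters are few and each sign is taken against the other clusters. Ranking over all macrophage-like cells gave 0.35 (0.27 to 0.38, 99.8th percentile of matched random lists) for NRF2 targets, with Hmox1 2.77-fold higher. It gave −0.31 for the glutathione system and −0.11 for all antioxidant genes. Clusters 2 and 5 were high in both NRF2 targets and dissociation genes, so that this ranking can restate the pattern and decides nothing. Handling as a cause of the differences between clusters stays open, and no biological explanation was tested, since the design names no group for one.

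Gene groups differed between CD9-high and CD9-low macrophage-like cells, which might reflect unspecific antibody binding, a mixture of clusters or handling. Binding without antigen is argued against as the whole cause for inflammatory and antioxidant genes. Terciles ranked by Cd9 mRNA gave medians of −0.24 (−0.29 to −0.18) and 0.19 (0.13 to 0.22), against −0.54 and 0.16 by antibody. However, the NRF2 median had the other sign (0.12 against −0.10). Interferon response genes (−0.46 by mRNA against −0.09 by antibody) and stromal resident genes (−0.84 against −0.06) also depended on the measure. The Cd9 mRNA ratio with CD206 matched was 6.38 (5.88 to 6.92). It concerns Cd9 alone and does not decide the cause for the other genes. Matching did have an effect: Mrc1, 1.69-fold higher in CD9-high cells without it, was lower with it. The CD206 means of the terciles (27.7 and 22.5 UMIs) do not tell how far CD206 differed between them. Such means can hang on 1 cell, since kept cells held up to 6365 CD206 UMIs. The CD206 mean was 49.9 in CD9 decile 3, against 6.34 and 10.6 in deciles 1 and 2. With dissociation genes matched, 75.5% (64.9 to 86.2%) of the inflammatory median was kept, which argues against handling as its whole cause as far as those genes measure it, although inflammatory genes went with dissociation genes (median log2 1.04 within clusters and 1.81 over all macrophage-like cells), so that a part stays open. Within clusters 53.3% (42.3 to 63.8%) of the inflammatory median and 53.2% (35.8 to 91.8%) of the antioxidant median were kept, intervals that span the 50% set beforehand, so the part due to the mixture of clusters stays open. No biological explanation was tested.

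Macrophage-like cells held more endocrine RNA than other immune cells, and the first 2 tests of this decided nothing: without the 10% of cells richest in endocrine and acinar RNA the list's median log2 ratio was 0.31 (0.09 to 0.40) rather than 1.48, between the bounds of 0 and 0.5, and at 8000 to 14000 RNA UMIs the median was 14 endocrine UMIs against 10 in lymphoid cells, a ratio of 1.4 between the bounds of 1.2 and 1.5, with medians of 12227 against 10127.5 RNA UMIs and endocrine shares of 0.118% against 0.100%. After these results the pattern was narrowed to cells with over 1% endocrine UMIs, which were 81 of 1666 macrophage-like cells (4.86%, 3.88 to 6.01%) and held 54.8% of the endocrine UMIs of the class, while the median share was 0.0973% in the other macrophage-like and 0.0981% in other immune cells. The tables argue against free RNA as the whole source: Ins2 UMIs outnumbered those of Gcg 164 to 1 in these cells and 10.7 to 1 in other immune cells, a ratio of 15.3 (12.3 to 19.1; 13.8 without the cell with the most Ins2), and over a limit of 0.5% there were 151 macrophage-like cells (9.06%, 7.73 to 10.5%) but 1 of 203 other immune cells (0.493%, 0.0125 to 2.71%), with 20.8% against 13.3% over 0.2%, whereas the 0 of 203 over 1% (at most 1.80%) decide nothing, since the highest of them reached 0.941%, and 2 of 24 endothelial-like (8.33%) and 49 of 237 unnamed, mostly low-depth cells (20.7%) also passed 1%. Doublets with an endocrine cell stay open. The Ins2 to Gcg ratio was 19.0 to 1 summed over all endocrine-like cells, which need not be that of the single cell in a doublet. The median RNA total of the macrophage-like cells over 1% was 1.07 times that of the other macrophage-like cells (22316 against 20769 UMIs), between the bounds of 1 and 1.2. Their median doublet score was 0.0276 against 0.0211, after the highest-scoring cells had been removed. Uptake of beta cell material could give such values too, and no biological explanation was tested.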
